A study of Mus musculus with 9 samples.

How the data were processed

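Cardiomyocytes were isolated at birth from pups of wild-type C57BL/6J mice whose mothers ate 1 of 3 diets during pregnancy, and 9 RNA-seq libraries, 3 per diet, were analysed. The authors deposited 1 table for 18738 genes whose values are TPM, as its name states and its column totals bear out. RSEM 1.3.1 and the genome build GRCm38 are named in the submitters' processing notes, which give them no role. The aligner and the gene annotation are not given in the sources used here. Messenger RNA was selected from total RNA before library construction, per the labels' protocols. Each column of the table sums to 1000000 TPM within rounding, all genes listed are of the mRNA type, and 0 mitochondrially encoded genes are among them, so that every value is relative to these genes alone. TPM does not keep the number of reads, so the depth of each library and its precision are unknown, and no interval that needs counts is given.

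The columns were matched to samples by name and number: CON was read as the normal diet, MID as the slight high-fat diet and HIGH as the high-fat diet, each with its replicate number. Nothing in the labels says that the 3 libraries of a diet come from separate litters or animals, so that p-values measure the spread between these samples, which may be technical. No pair of libraries was identical.

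Expression was taken as log2(TPM + 1) with no further scaling, and 13655 genes with a mean of at least 1 TPM over the 9 libraries were tested. Fold changes are on the log2(TPM + 1) scale, which understates those of low genes. A linear model with the 3 diets was fitted to all 9 libraries in limma 3.58.1 under R 4.3.3, with 6 residual degrees of freedom and an intensity trend on the variance, and p-values were two-sided and adjusted by the Benjamini-Hochberg method with a threshold of 0.05. An exact permutation test of 3 against 3 libraries cannot give a two-sided p below 0.1, and no single gene was tested that way. Transcript positions were taken from the RefSeq table of GRCm38.p6 matched on the Entrez identifiers of the table.

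Gene lists, 33 in number, were fixed before the data were examined, as were the samples, the tests, the rule for named genes and all alternatives other than those said to be added later. They covered DNA replication, mitosis, cell-cycle brakes, mature sarcomere, fetal and stress-associated cardiac genes, calcium handling, cardiac transcription factors, fatty acid oxidation, PPAR-responsive genes, cholesterol and fatty acid synthesis, glycolysis, nuclear respiratory chain, mitochondrially encoded genes, insulin and IGF signalling, Hippo-YAP targets, imprinted genes, antioxidant genes, ER stress, inflammation, hypoxia, immediate-early and heat-shock genes, circadian and glucocorticoid genes and ribosomal proteins. Markers of fibroblasts, endothelium, smooth muscle and pericytes, epicardium, immune cells, red cells, atrium, skeletal muscle and of lung, thymus and brown fat were included for other cells an isolate could hold, beside sex-linked genes. The 30 lists with at least 4 measured members, sex-linked genes apart, were tested with camera of limma at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry, which asks whether a list's genes move on balance one way. List p-values were adjusted over the lists of a comparison. Sex-linked genes were given as values only. Some genes are shared between lists, such as Slc2a1, Pdk1, Gadd45b and Cnn1, so the list results are not independent of each other.

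Named genes had a mean of at least 5 TPM and a symbol that is not a clone or predicted name. They were the 10 largest rises and 10 largest falls in HFD vs ND, and 5 and 5 in the other comparisons, among genes past the threshold whose libraries did not overlap. Where fewer passed, the list was filled to 5 and 5 with the smallest p among genes whose libraries did not overlap. The 3 members of each list with the smallest p in HFD vs ND and 17 fixed genes of proliferation, cardiac identity, metabolism and cell type were added. Some genes that meet this rule are not reported here. Genes listed at 0 in a whole diet were given no fold. Hba-a1, Hbb-bs, Hspa1b and Ccl21a have near-identical copies between which reads could have been split, and are reported as uncertain.

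The test was checked on simulated data drawn around the mean of each gene with its spread within diets. In 13655 simulated genes for HFD vs ND it recovered 2 of 67 genes changed by a log2 of 0.5, 33 of 67 changed by 1 and 65 of 66 changed by 2, with 7 false calls among 107. For HFD vs sHFD it recovered 0 of 67, 36 of 67 and 64 of 66, with 3 false calls among 103. Few genes were changed, which makes the adjustment stricter than in the data, where 1484 genes passed in HFD vs ND and 4665 in HFD vs sHFD. The recovery at each size therefore does not carry over to the data. The list test called 0 of 30 lists with no change, and with 1 list raised by a log2 of 0.5 it called that list and 0 others. Genes were drawn independently, without the correlation within lists, so the checks say nothing about false list calls that such correlation brings at the preset value of 0.01. Nor do they cover false gene calls from shifts shared across a library.

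Alternatives were a pseudocount of 0.1 or 5, no filter or a mean of at least 5 TPM, median-ratio scaling, quantile normalization, rescaling without 10 haemoglobin genes, a fit of only the 2 diets compared, no variance trend, a robust trend, array weights, the replicate number as a block, a fold of at least 2 as well, and leaving out each library in turn. Added after seeing the data were the removal of a lowess trend on transcript GC content from each library, possible for 97.8% of the genes kept, and the mean log2 level of the immediate-early and heat-shock list as a covariate. Transcript GC content and length were taken from the GENCODE annotation of GRCm38.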

Results

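The data were 9 RNA-seq libraries of cardiomyocytes isolated at birth from the hearts of wild-type C57BL/6J mouse pups. Their mothers had been assigned at random to a normal diet (ND), a slight high-fat diet (sHFD) or a high-fat diet (HFD) for the whole of pregnancy, and each diet had 3 libraries. Expression was given in TPM, a unit relative to the library total, for 18738 protein-coding genes, of which 16722 to 17105 were above 0 in a library. TPM keeps no read depth, so the depth of each library is unknown. The 20 most abundant genes took 9.19% to 12.5% of the total. No pair of libraries held identical values, and Pearson correlations of log2(TPM + 1) between libraries ran from 0.929 to 0.992. The comparisons ask which genes differ in newborn heart muscle cells after a maternal high-fat diet, a question the series ties to cardiomyocyte proliferation.

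The HFD libraries lay together at an end of the first principal component, with ND replicate 1 nearest to them. This component held 61.2% of the variance and placed the 3 HFD libraries between -43.8 and -41.4 and the 3 sHFD libraries between 31.2 and 37.4. The ND libraries were spread along it, with ND replicate 1 at -24.5, replicate 3 at 16.0 and replicate 2 at 35.3. ND replicate 1 had a mean correlation of 0.980 with the HFD libraries and of 0.962 with the other ND libraries. The mean log2 level of the immediate-early and heat-shock genes, transcripts that rise within minutes of cell stress, was 8.47 in ND replicate 1, 6.64 in replicate 2 and 7.65 in replicate 3. It was 6.62, 6.74 and 6.76 in the sHFD libraries and 8.11, 8.09 and 8.66 in the HFD libraries. Among sex-linked genes, the Y-linked Ddx3y was 13.6 TPM in sHFD replicate 3 and 33.8 to 61.7 TPM in the other libraries.

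**Figure D1:**
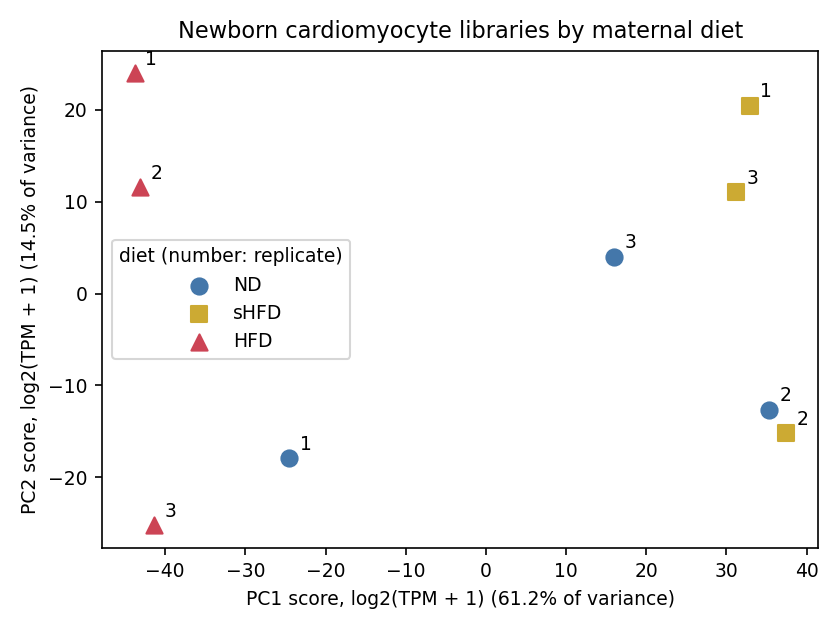
Scores of the 9 libraries on the first 2 principal components of log2(TPM + 1), with 1 point per library, coloured by maternal diet and numbered by replicate. The HFD libraries lie at one end of the first component, the sHFD libraries at the other, and ND replicate 1 at -24.5 lies on the HFD side.

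Against ND, some ventricular stress genes and mitosis genes were higher in HFD cardiomyocytes and some lipid handling genes and immune cell markers were lower. No list of the 30 tested passed camera's test with an estimated correlation, against 23 with a preset one. Nppb, the B-type natriuretic peptide made by stretched ventricular muscle, rose from 72.5 ± 29.7 TPM in ND to 759 ± 238 TPM in HFD (SD, n = 3 each), a log2 fold change of 3.41 (SE 0.37, limma adjusted p = 0.00139). Myh7, the beta-myosin heavy chain of the fetal mouse ventricle, rose from 304 ± 176 to 1115 ± 146 TPM (log2 2.01, SE 0.34, adjusted p = 0.00919). Car3, a carbonic anhydrase of muscle and fat, fell from 16.0 ± 1.58 to 1.18 ± 0.24 TPM (log2 -2.96, SE 0.19, adjusted p = 1.25e-05). Aqp7, a glycerol channel, fell from 19.9, 45.6 and 42.6 TPM in the ND libraries to 4.51 ± 0.80 TPM in HFD (log2 -2.67, SE 0.27, adjusted p = 0.000795).

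Of 13655 genes tested with limma, 1484 passed an adjusted p of 0.05, of which 175 were higher and 1309 lower in HFD, and 581 of them also changed at least 2-fold. The HFD and ND libraries did not overlap in 27.9% of genes, where chance gives 10%. The median log2 fold change of all genes was -0.14, and list medians below are given relative to it. When each library was scaled to a common median ratio the count was 1526 with 582 higher and 944 lower, and quantile normalization gave 427 higher and 637 lower. The count rested on single libraries: it was 3842 without ND replicate 1, 624 without ND replicate 2, 39 without ND replicate 3, 877 without sHFD replicate 3, 127 without HFD replicate 1 and 32 without HFD replicate 2. In each of these fits with a library left out the 1484 genes kept their direction, and 28 of them passed the test in every one.

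The 10 largest rises among well-expressed genes whose libraries did not overlap were Nppb, Cxcl1, Tent5b, Myh7, Il6, Gadd45b, Ankrd1, Ccn2, Nek2 and Cxcl10. Ankrd1, a stretch-responsive protein of the sarcomere and nucleus, rose from 463 ± 78.7 to 1210 ± 165 TPM (log2 1.39, SE 0.19, adjusted p = 0.00403). Tent5b, of a family of non-canonical poly(A) polymerases, rose by 2.12 (SE 0.31, adjusted p = 0.0061), and Nek2, a centrosome kinase, by 1.35 (SE 0.27, adjusted p = 0.0132). The chemokines Cxcl1 and Cxcl10, the cytokine Il6, the growth-arrest gene Gadd45b and the matricellular gene Ccn2 rose by between 1.32 and 2.32, with adjusted p from 0.0176 to 0.037. In each of them ND replicate 1 was the highest ND library, as in Gadd45b (109, 18.2 and 47.3 TPM in ND replicates 1 to 3). Of the 9 fits with a library left out, Gadd45b passed in 2, Cxcl10 in 3, Il6 in 4, Ccn2 in 5 and Cxcl1 in 6. Il6 missed the threshold once a trend on GC content was removed (adjusted p = 0.0575) and Gadd45b did so under quantile normalization (adjusted p = 0.0537). The largest falls included Car3, Aqp7, Ucp3, Cx3cr1, Cyp26a1, Slc25a34, Gimap4, Ccl21a and Sbk2. Ucp3, a mitochondrial uncoupling protein of muscle, was 1.28, 16.0 and 4.88 TPM in the ND libraries and 0.23, 0 and 0.20 TPM in the HFD libraries (adjusted p = 0.0148). Gimap4, a GTPase of lymphoid cells, changed by -2.10 (SE 0.26, adjusted p = 0.00215), Cx3cr1, the fractalkine receptor of macrophages, by -2.35 (SE 0.43, adjusted p = 0.0106), and Cyp26a1, which degrades retinoic acid, by -2.13 (SE 0.33, adjusted p = 0.00755). Slc25a34, a mitochondrial carrier, and Sbk2, a kinase, changed by -2.13 and -2.01 (adjusted p = 0.0129 and 0.00867). Ccl21a, a lymphatic chemokine with near-identical gene copies and therefore uncertain, changed by -2.09 (adjusted p = 0.0497) and missed the threshold under median-ratio scaling, quantile normalization and removal of the GC trend (adjusted p = 0.0635, 0.0714 and 0.0805). Nppb, Tent5b, Ankrd1, Car3, Aqp7 and Gimap4 passed in all 9 fits with a library left out. Of the 20 genes with the largest changes by the same rule, 20 passed without ND replicate 1, 15 without ND replicate 2, 6 without ND replicate 3, 19 without sHFD replicate 1 or 2, 16 without sHFD replicate 3, 10 without HFD replicate 1, 6 without HFD replicate 2 and 19 without HFD replicate 3.

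**Figure D2:**
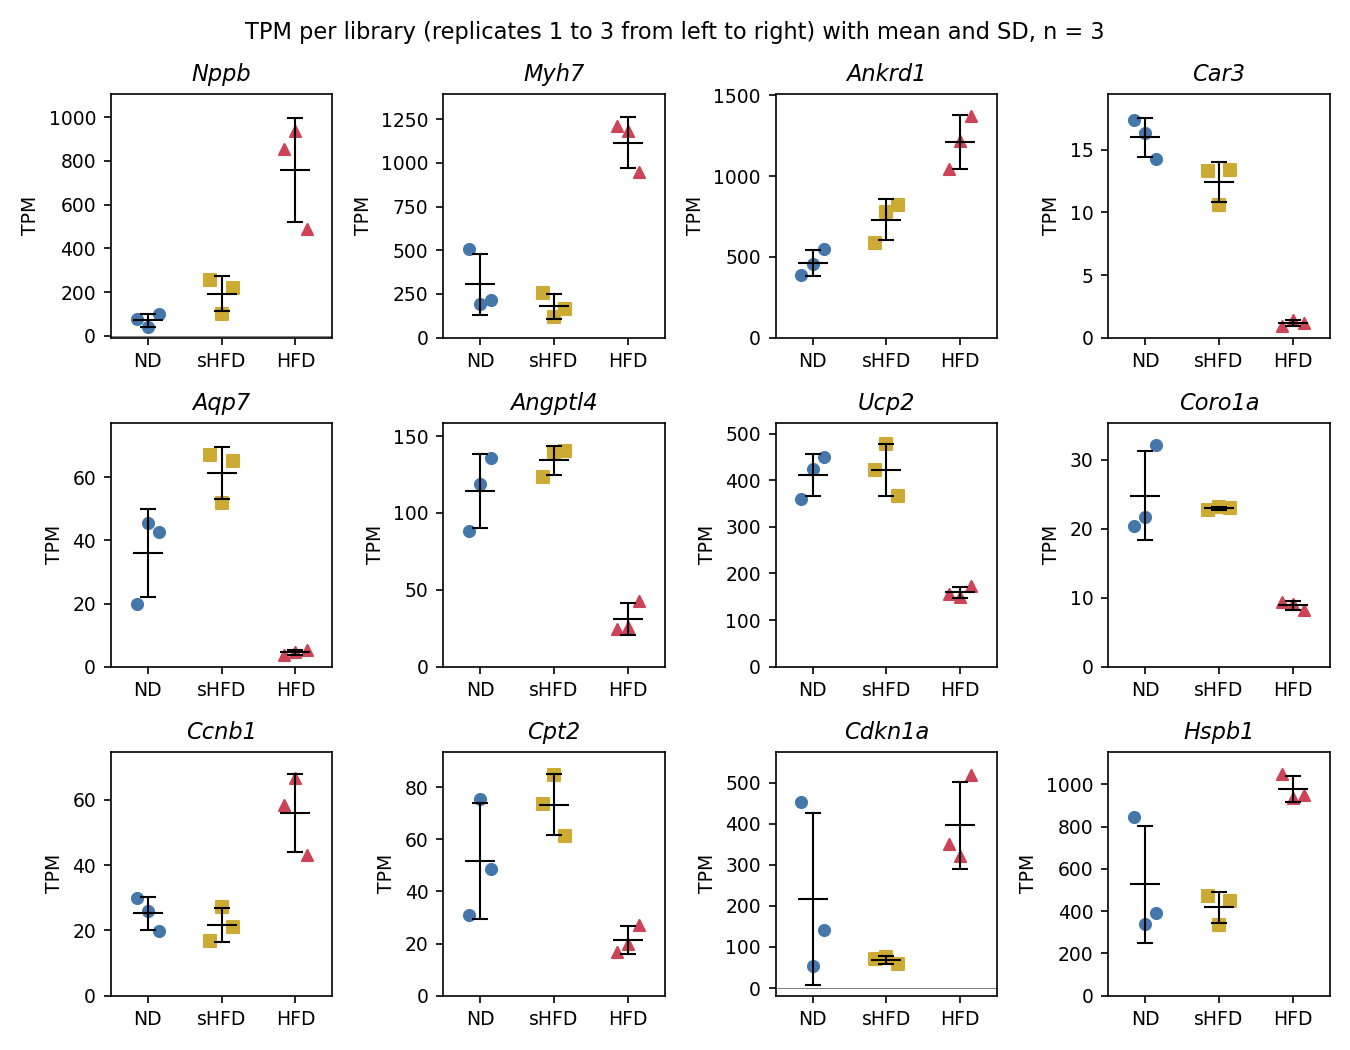
TPM of 12 genes in each library by maternal diet (points, replicates 1 to 3 from left to right), with the mean and SD of each diet as bars (n = 3) on linear axes. Nppb, Myh7 and Ankrd1 are higher in the HFD libraries than in the other 6, Car3, Aqp7, Angptl4, Ucp2 and Coro1a are lower, and ND replicate 1 lies near the HFD libraries for Cdkn1a and Hspb1.

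Nppb lies on chromosome 4 (147985786 to 147987205), Myh7 on chromosome 14 (54970684 to 54994626), Ankrd1 on chromosome 19 (36111965 to 36119844), Car3 on chromosome 3 (14863538 to 14872381) and Aqp7 on chromosome 4 (41033074 to 41048237), as 1-based GRCm38 positions.

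Of 20 fetal and stress-associated cardiac genes, 5 rose and 1 fell over all genes tested, and 6 rose and 1 fell when adjusted over the list alone. The 3 with the smallest p were Nppb, Ankrd1 and Myh7. Nppa, the atrial natriuretic peptide, was 8683 ± 1215 TPM in ND and 13111 ± 3996 TPM in HFD (log2 0.55, SE 0.29, adjusted p = 0.222). As a group they lay 0.44 above all genes in the median (camera adjusted p = 9.24e-06, adjusted p = 0.153 with an estimated correlation), and fry gave an adjusted p of 0.0341 for a shared direction. Of 25 mature sarcomere genes 1 rose, Cryab, a small heat-shock protein of the Z-disc (log2 0.82, SE 0.19, adjusted p = 0.0217), and 1 when adjusted over the list alone. The list's median lay 0.21 above that of all genes (camera adjusted p = 0.0144, adjusted p = 0.632 with an estimated correlation). Myh6, the adult alpha-myosin heavy chain, had a log2 difference of 0.11 (SE 0.24, adjusted p = 0.796) and Tnnt2, cardiac troponin T, one of 0.09 (SE 0.25, adjusted p = 0.843). Among 23 cardiac transcription factors, Srf, the serum response factor, rose (log2 0.55, adjusted p = 0.0333) and Prdm16, a chromatin regulator of compact myocardium, fell (log2 -0.84, adjusted p = 0.0478), and 0 passed when adjusted over the list alone, against 2 over all genes and 7 at an unadjusted p under 0.05. Prdm16 missed the threshold under median-ratio scaling, quantile normalization and removal of the GC trend (adjusted p = 0.0561, 0.103 and 0.068). Tbx5, a T-box factor (log2 0.70, adjusted p = 0.0568), passed it under all 3 (adjusted p = 0.0248, 0.0478 and 0.0225). This list's median lay 0.19 above that of all genes (camera adjusted p = 0.0423, adjusted p = 0.632 with an estimated correlation). None of 29 calcium handling and ion channel genes passed limma's test over all genes or when adjusted over the list alone, against 3 at an unadjusted p under 0.05. The list lay 0.07 above other genes (camera adjusted p = 0.367) although its own median log2 fold change was -0.07. The ATP-sensitive potassium channel gene Kcnj11 in that list had a log2 difference of -0.80 (SE 0.26, adjusted p = 0.061).

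Of 42 G2/M and mitosis genes, 12 rose and 0 fell over all genes tested, and 23 rose when adjusted over the list alone. Ccnb1, the mitotic cyclin B1, rose from 29.8, 25.9 and 19.9 TPM in the ND libraries to 58.4, 66.6 and 43.0 TPM in the HFD libraries (log2 1.12, SE 0.22, adjusted p = 0.0141), and the ubiquitin-conjugating enzyme gene Ube2c and the spindle kinase gene Aurka rose by 0.79 and 1.02 (adjusted p = 0.0141 and 0.0203). Mitosis genes lay 0.70 above all genes in the median (camera adjusted p = 1.63e-16, adjusted p = 0.409 with an estimated correlation). Mki67, the proliferation marker, was 51.1 ± 12.2 TPM in ND and 79.9 ± 9.53 TPM in HFD (log2 0.66, SE 0.22, adjusted p = 0.0696), and passed under median-ratio scaling and with the GC trend removed. Of 40 DNA replication and G1/S genes, 1 fell over all genes tested and 0 when adjusted over the list alone, against 16 at an unadjusted p under 0.05. The gene that fell was Lig1, DNA ligase I (log2 -0.83, SE 0.23, adjusted p = 0.0368), which missed the threshold under median-ratio scaling, quantile normalization and removal of the GC trend (adjusted p = 0.0507, 0.0663 and 0.0631). Replication genes had a median of -0.28 relative to all genes (camera adjusted p = 0.0146, adjusted p = 0.695 with an estimated correlation). Ccnd1, the G1 cyclin D1, fell (log2 -0.78, SE 0.21, adjusted p = 0.0339) but missed the threshold under median-ratio scaling and quantile normalization (adjusted p = 0.0505 and 0.0511). Ccnd2, cyclin D2, had a log2 difference of -0.88 (SE 0.27, adjusted p = 0.0526) and passed without the haemoglobin genes and with the GC trend removed. Of 27 cell-cycle brakes, 5 rose and 1 fell over all genes, and 7 rose and 2 fell when adjusted over the list alone. Tob1, an antiproliferative protein, and Cdkn2d, an inhibitor of cyclin D kinases, rose by 1.00 and 0.67 (adjusted p = 0.0226 and 0.0238), and Trp53, encoding p53, changed by -1.17 (SE 0.21, adjusted p = 0.0105). Cdkn1a, encoding p21, was 454, 54.6 and 142 TPM in the ND libraries and 351, 321 and 518 TPM in the HFD libraries (log2 1.34, SE 0.52, adjusted p = 0.103). The brakes' median lay 0.46 above that of all genes (camera adjusted p = 1.54e-05, adjusted p = 0.409 with an estimated correlation). Relative to the other ND libraries, ND replicate 1 differed by 0.24 in the mitosis list, by -0.43 in the replication list and by 0.45 in the brakes, each in the direction of HFD. It went with HFD minus the ND mean, which contains ND replicate 1, in 18 of 31 lists and against it in 13, and with HFD minus the mean of the other ND libraries, which both differences then share, in 21 and against it in 10. Against both went the sarcomere (-0.34), glycolysis (-0.24), respiratory chain (-0.40) and atrial (-0.26) lists among others. These tallies go by sign alone. HFD minus the mean of the other ND libraries was only 0.0036 in the respiratory chain list. It was -0.0008 in the calcium handling list, which counts as going with it.

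Of 21 PPAR-responsive and lipid-storage genes, 10 fell and 0 rose over all genes tested, and 14 fell when adjusted over the list alone. Ucp2, a mitochondrial uncoupling protein, fell from 411 ± 45.6 to 160 ± 11.9 TPM (log2 -1.35, SE 0.16, adjusted p = 0.00139), Angptl4, an inhibitor of lipoprotein lipase, from 114 ± 24.1 to 31.1 ± 10.3 TPM (log2 -1.87, SE 0.22, adjusted p = 0.00139), and Lipe, hormone-sensitive lipase, also fell (log2 -1.13, SE 0.18, adjusted p = 0.00755). Pdk4, a PPAR-driven kinase that restrains glucose oxidation, had a log2 difference of -0.28 (SE 0.31, adjusted p = 0.581). PPAR genes had a median of -0.59 relative to all genes (camera adjusted p = 9.24e-06, adjusted p = 0.409 with an estimated correlation), and fry gave an adjusted p of 0.0341. Of 30 fatty acid uptake and oxidation genes, 7 fell and 0 rose over all genes, and 11 fell and 1 rose when adjusted over the list alone. Ech1, a peroxisomal and mitochondrial isomerase of beta-oxidation, Mlycd, malonyl-CoA decarboxylase, and Cpt2, a carnitine palmitoyltransferase, changed by -0.89, -1.17 and -1.17 (adjusted p = 0.0174, 0.0195 and 0.0215), Mlycd missing the threshold once a trend on GC content was removed (adjusted p = 0.0565). Cpt1a, the liver-type gatekeeper of mitochondrial fatty acid import, fell (log2 -1.02, SE 0.24, adjusted p = 0.0223), and Cpt1b, the muscle type, had a log2 difference of -0.48 (SE 0.22, adjusted p = 0.171). The oxidation list's median lay at -0.39 relative to all genes (camera adjusted p = 0.00054, adjusted p = 0.591 with an estimated correlation). ND replicate 1 differed from the other ND libraries by -0.56 in the oxidation list and by -0.40 in the PPAR list. Of 31 cholesterol and fatty acid synthesis genes, 4 fell over all genes and 6 when adjusted over the list alone, among them the sterol pathway genes Mvk and Dhcr7 and the desaturase gene Fads2 (log2 -0.83, -1.09 and -0.72), and the list's median of -0.16 relative to all genes did not set it apart (camera adjusted p = 0.315). Mvk missed the threshold under quantile normalization (adjusted p = 0.0663).

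Of 27 glycolysis genes 3 rose over all genes and 3 when adjusted over the list alone: Slc2a1, the basal glucose transporter, Pdk1, a kinase of pyruvate dehydrogenase, and Pgk1, phosphoglycerate kinase (log2 0.59, 0.60 and 0.68), the last 2 missing the threshold under quantile normalization. Glycolysis genes lay 0.35 above all genes in the median (camera adjusted p = 0.000659, adjusted p = 0.486 with an estimated correlation). Of 20 hypoxia genes, 3 rose and 1 fell over all genes, and 4 rose and 2 fell when adjusted over the list alone, with Bnip3, a mitophagy receptor, up by 0.86 (adjusted p = 0.0199). The other genes that rose over all genes were Slc2a1 and Pdk1, which are also in the glycolysis list. The hypoxia median lay 0.39 above that of all genes (camera adjusted p = 0.000289, adjusted p = 0.29 with an estimated correlation). None of 54 nuclear respiratory chain genes passed limma's test over all genes, when adjusted over the list alone or at an unadjusted p under 0.05. Their median was 0.13 above that of all genes (camera adjusted p = 0.0512), while the list's own median log2 fold change was -0.01, and Uqcrc1, a core subunit of complex III, had a log2 difference of -0.18 (SE 0.17, adjusted p = 0.514). Mitochondrially encoded genes numbered 0 in the table.

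Of 23 immune cell markers, 16 fell and 0 rose over all genes tested, and 20 fell when adjusted over the list alone. Coro1a, a leukocyte actin regulator, fell from 24.7 ± 6.46 to 8.86 ± 0.63 TPM (log2 -1.36, SE 0.19, adjusted p = 0.00489). Cd74, the invariant chain of class II antigen presentation, fell by 1.47 (SE 0.24, adjusted p = 0.00824) and Csf1r, the macrophage growth factor receptor, by 1.41 (SE 0.23, adjusted p = 0.00867). Ptprc, the pan-leukocyte antigen, changed by -0.94 (SE 0.24, adjusted p = 0.0302) and missed the threshold under quantile normalization. Immune markers had a median of -0.76 relative to all genes (camera adjusted p = 3.4e-08, adjusted p = 0.409 with an estimated correlation), and fry gave an adjusted p of 0.0341. Of 23 endothelial markers, 5 fell over all genes and 5 when adjusted over the list alone, among them Aplnr, the apelin receptor, from 198 ± 13.6 to 75.2 ± 3.23 TPM (log2 -1.38, SE 0.14, adjusted p = 0.000795), the transcription factor gene Sox18 (log2 -1.22) and the adhesion gene Icam2 (log2 -0.91). Pecam1, the general endothelial marker, had a log2 difference of 0.05 (SE 0.18, adjusted p = 0.893), and the list's median lay at -0.06 (camera adjusted p = 0.0258, adjusted p = 0.519 with an estimated correlation). ND replicate 1 differed from the other ND libraries by 0.32 in the endothelial list. HFD minus the mean of ND replicates 2 and 3 gave it a median of 0.01 relative to all genes. Of 14 smooth muscle and pericyte markers, 5 fell and 1 rose over all genes, and 6 fell and 1 rose when adjusted over the list alone. The pericyte genes Kcnj8, a potassium channel subunit, and Rgs5, a G protein regulator, changed by -1.28 and -1.04 (adjusted p = 0.00403 and 0.0195). The contractile gene Cnn1, calponin, rose by 1.01 (adjusted p = 0.0271) but missed the threshold under quantile normalization (adjusted p = 0.0535). Pericyte and smooth muscle markers as a list did not stand apart (median -0.35, camera adjusted p = 0.245).

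None of 29 fibroblast and matrix markers passed limma's test over all genes or when adjusted over the list alone, against 5 of them at an unadjusted p under 0.05. Their median lay at -0.03 (camera adjusted p = 0.655). Col1a1, a chain of type I collagen, had a log2 difference of -0.07 (SE 0.22, adjusted p = 0.874). Of 13 epicardial markers, 1 rose and 1 fell over all genes, and 4 rose and 1 fell when adjusted over the list alone. Upk1b, a uroplakin of mesothelium, rose by 0.80 (adjusted p = 0.0443) and Aldh1a2, the retinoic acid synthesis enzyme, changed by -0.86 (adjusted p = 0.0352), missing the threshold under median-ratio scaling and quantile normalization. The epicardial median lay 0.53 above that of all genes (camera adjusted p = 0.000186, adjusted p = 0.432 with an estimated correlation). Of 11 erythroid markers, 1 fell over all genes and 7 when adjusted over the list alone. Alas2, the red cell enzyme of haem synthesis, changed by -0.99 (SE 0.22, adjusted p = 0.0176), and Hbb-bs, an adult beta globin with a close copy and so uncertain, was 3975 ± 2276 TPM in ND and 1896 ± 508 TPM in HFD (adjusted p = 0.0746). The erythroid median lay at -0.65 (camera adjusted p = 0.0276, adjusted p = 0.486 with an estimated correlation), and ND replicate 1 differed from the other ND libraries by -0.54 in it. None of 14 atrial markers passed limma's test over all genes or when adjusted over the list alone, against 3 at an unadjusted p under 0.05 (median 0.26, camera adjusted p = 0.105). Of 9 skeletal muscle markers, 1 rose over all genes and 2 when adjusted over the list alone: Myh8, the perinatal myosin heavy chain, rose by 1.21 (SE 0.22, adjusted p = 0.0101). That list's median lay 0.38 above all genes (camera adjusted p = 0.00282, adjusted p = 0.228 with an estimated correlation), and fry gave an adjusted p of 0.0422. Of the lung, thymus and brown fat markers 3 were measured and 0 passed limma's test over all genes or when adjusted over the list alone, and of the sex-linked genes 4 were measured and 0 passed.

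Stress and signalling lists followed. Of 27 immediate-early and heat-shock genes, 2 rose over all genes and 2 when adjusted over the list alone: Hsp90aa1, an inducible chaperone (log2 0.82, SE 0.22, adjusted p = 0.0332), and Hspb1, a small heat-shock protein (log2 1.01, SE 0.28, adjusted p = 0.0367). Hspb1 missed the threshold under quantile normalization. Hspa1b, an inducible chaperone with a near-identical copy and so uncertain, was 1527, 40.2 and 229 TPM in the ND libraries (log2 2.59, SE 0.88, adjusted p = 0.0707). The list's median lay 0.57 above that of all genes (camera adjusted p = 1.69e-08, adjusted p = 0.432 with an estimated correlation), and ND replicate 1 differed by 1.21 from the other ND libraries in it. Of 22 circadian and glucocorticoid genes, 1 fell over all genes and 1 when adjusted over the list alone, the clock output gene Dbp (log2 -0.74, adjusted p = 0.0233), which missed the threshold under quantile normalization and with the GC trend removed (adjusted p = 0.0615 and 0.0706). The list's median lay 0.67 above all genes (camera adjusted p = 9.24e-06, adjusted p = 0.432 with an estimated correlation). ND replicate 1 differed by 0.79 in this list. Of 28 inflammation and interferon genes, 4 rose and 3 fell over all genes, and 4 rose and 3 fell when adjusted over the list alone. Beside Cxcl1, the stromal chemokine gene Cxcl12 changed by -0.74 (adjusted p = 0.017). The list's median lay 0.25 above all genes (camera adjusted p = 0.0293, adjusted p = 0.486 with an estimated correlation), and ND replicate 1 differed by 0.33 in it. Of 19 Hippo-YAP targets, 5 rose over all genes and 6 when adjusted over the list alone, among them the junction gene Amotl1 (log2 0.70, adjusted p = 0.0127), Ccn2 and the tissue factor gene F3 (log2 0.88, adjusted p = 0.03). Their median lay 0.47 above all genes (camera adjusted p = 1.54e-05, adjusted p = 0.432 with an estimated correlation), and ND replicate 1 differed by 0.27.

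Among 23 antioxidant and NRF2 targets 1 rose over all genes and 0 when adjusted over the list alone, against 5 at an unadjusted p under 0.05. The gene that rose was Mt2, a metallothionein (log2 1.44, adjusted p = 0.0385), which missed the threshold under quantile normalization (adjusted p = 0.0647). Antioxidant genes as a list did not stand apart (median 0.17, camera adjusted p = 0.0588). None of 27 ER stress genes passed limma's test over all genes or when adjusted over the list alone, against 7 at an unadjusted p under 0.05. Hspa5, the ER chaperone BiP, had a log2 difference of 0.66 (adjusted p = 0.0664) and passed under median-ratio scaling (adjusted p = 0.0394). The ER stress median lay 0.26 above all genes (camera adjusted p = 0.00655, adjusted p = 0.432 with an estimated correlation). Of 26 insulin and IGF genes, 1 fell over all genes and 0 when adjusted over the list alone, against 11 at an unadjusted p under 0.05. The gene that fell was Igfbp7, a binding protein (log2 -0.59, adjusted p = 0.049), which missed the threshold under median-ratio scaling and with the GC trend removed. The list's median lay 0.23 above all genes (camera adjusted p = 0.00832, adjusted p = 0.486 with an estimated correlation), and ND replicate 1 differed by 0.29 from the other ND libraries in it. Of 16 imprinted growth genes 1 rose over all genes and 1 when adjusted over the list alone, the zinc finger gene Zim1 (log2 0.85, adjusted p = 0.0369), and Igf2, the fetal growth factor, had a log2 difference of -0.03 (SE 0.19, adjusted p = 0.931). That median lay 0.19 above all genes (camera adjusted p = 0.0352, adjusted p = 0.486 with an estimated correlation). None of 44 cytosolic ribosomal protein genes passed limma's test over all genes, when adjusted over the list alone or at an unadjusted p under 0.05 (median 0.18, camera adjusted p = 0.00912, adjusted p = 0.695 with an estimated correlation).

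**Figure D3:**
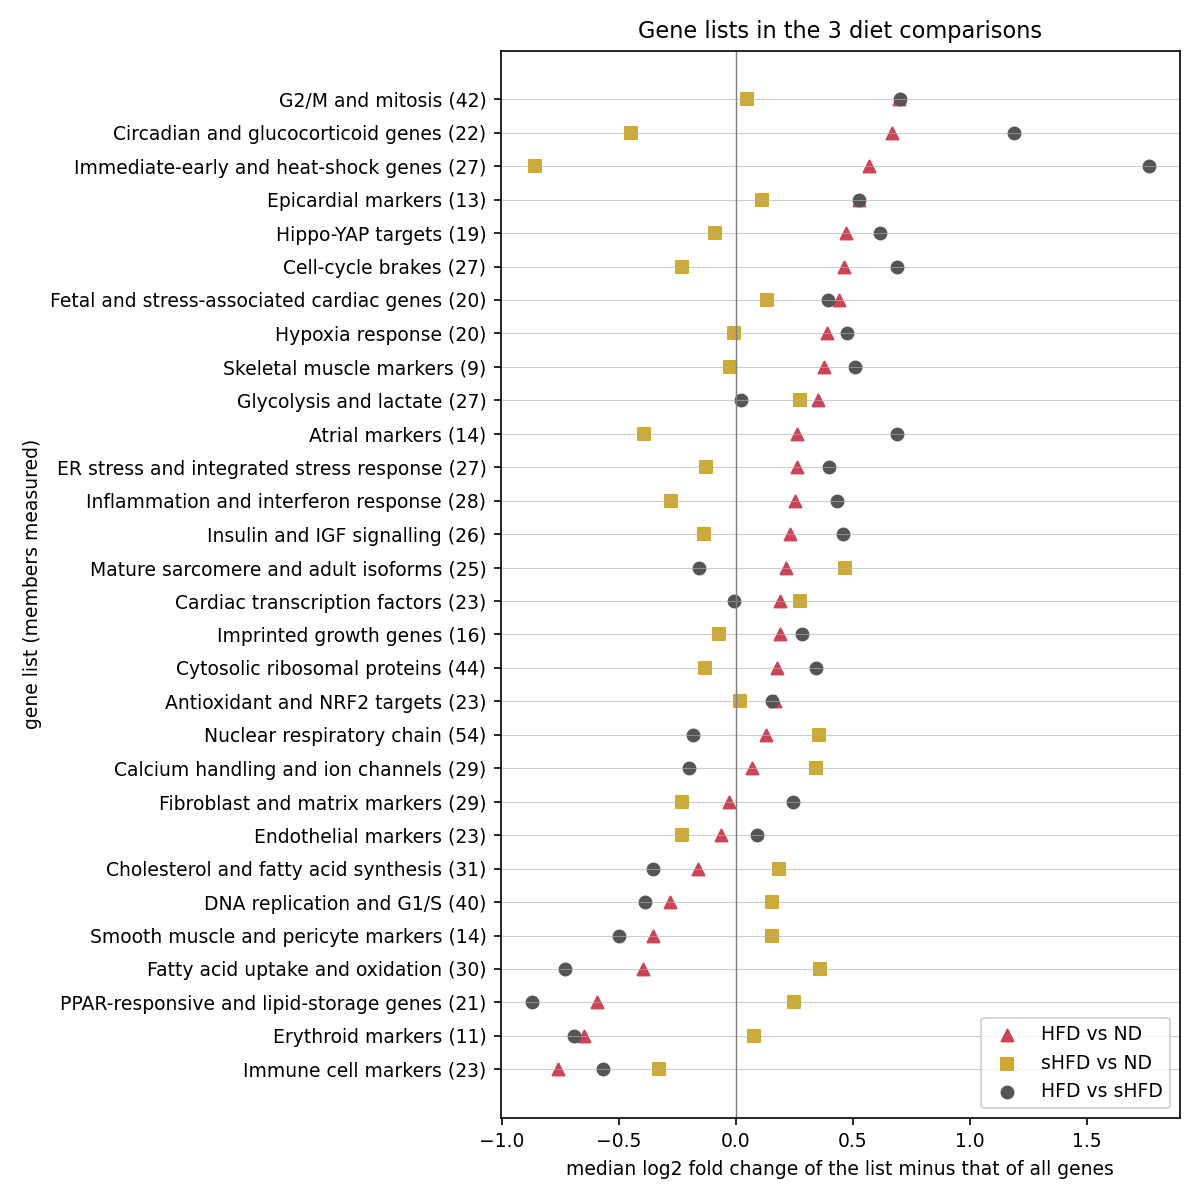
Median log2 fold change of each of 30 gene lists minus the median of all genes, in the 3 diet comparisons (triangles, squares and circles), with the number of members measured in brackets. In HFD vs ND the mitosis list has the highest median at 0.70 and the immune cell list the lowest at -0.76.

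In all, 23 of 30 lists passed camera's test with a preset correlation of 0.01 in HFD vs ND, 17 higher and 6 lower, against 0 with an estimated correlation and 4 with fry. Under quantile normalization the sarcomere, transcription factor, glycolysis, insulin, imprinted, ER stress, inflammation and ribosomal lists no longer passed and 15 lists did. The endothelial and inflammation lists no longer passed under median-ratio scaling (camera adjusted p = 0.0608 and 0.124). With the GC trend removed, these and the imprinted list no longer passed (camera adjusted p = 0.0905, 0.163 and 0.0591). Neither did the erythroid list without the haemoglobin genes (camera adjusted p = 0.29). Of the 70 named genes called in this comparison, 68 passed without ND replicate 1, 43 without ND replicate 2, 11 without ND replicate 3, 60 without sHFD replicate 1, 63 without sHFD replicate 2, 52 without sHFD replicate 3, 21 without HFD replicate 1, 11 without HFD replicate 2 and 59 without HFD replicate 3. Among the list members above, Ucp2, Angptl4, Aplnr, Kcnj8 and Coro1a passed in all 9 of these fits. With the mean log2 level of the immediate-early and heat-shock genes added to the model, a covariate chosen after the values were seen, 512 genes passed in HFD vs ND, 63 higher and 449 lower.

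The slight high-fat diet was set against the normal diet to ask whether a milder exposure already changes expression. Only 1 gene passed limma's test among 13655, against 1005 at an unadjusted p under 0.05: Gm5796, a predicted gene named here after its values were seen, which was 4.34, 2.92 and 3.86 TPM in the ND libraries and 0, 0.46 and 0 TPM in the sHFD libraries (log2 -2.04, SE 0.25, adjusted p = 0.0211). The sHFD and ND libraries did not overlap in 9.40% of genes, where chance gives 10%. Without sHFD replicate 1 the gene that passed was another one. The count was 0 without ND replicate 1, ND replicate 3 or sHFD replicate 3, 2 without HFD replicate 2 and 360 without ND replicate 2.

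The well-expressed genes with the smallest p and no overlap between these libraries missed the threshold. On the higher side these were Nnt, the mitochondrial transhydrogenase in which this mouse strain is known to carry a deletion (62.7, 121 and 69.3 TPM in the ND libraries and 182 ± 21.2 TPM in sHFD, log2 1.16, SE 0.21, adjusted p = 0.366), Plin4, a lipid droplet coat protein (log2 1.20, adjusted p = 0.548), Fbxl22, a muscle ubiquitin ligase subunit (log2 0.84), Frmd5, a membrane-cytoskeleton linker (log2 1.40), and Ppargc1b, a coactivator of mitochondrial genes (log2 1.00). On the lower side they were Spp1, osteopontin (41.9 ± 14.4 TPM in ND and 12.2 ± 5.21 TPM in sHFD, log2 -1.71, SE 0.28, adjusted p = 0.282), the immediate-early factor gene Egr2 (log2 -1.55, adjusted p = 0.504), the exchange factor gene Rasgef1b (log2 -1.13), the matrix gene Matn4 (log2 -1.31) and the mast cell chymase gene Cma1 (log2 -0.86).

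No member of any list passed over all genes in sHFD vs ND. Adjusted over the list alone, 17 of 27 immediate-early and heat-shock genes were lower, as were 7 of 28 inflammation genes, and 4 of 20 fetal and stress-associated cardiac genes, 2 of 23 cardiac transcription factors, 1 of 21 PPAR genes and 1 of 14 smooth muscle genes were higher. The immediate-early and heat-shock median lay at -0.86 relative to all genes (camera adjusted p = 2.42e-17, adjusted p = 0.436 with an estimated correlation). The respiratory chain median lay 0.36 above all genes, with 54 of 54 members above 0 (camera adjusted p = 1.1e-14, adjusted p = 0.436 with an estimated correlation). The mature sarcomere median lay 0.47 above (camera adjusted p = 1.19e-09) and the fatty acid oxidation median 0.36 above (camera adjusted p = 2.93e-08), each with an adjusted p = 0.436 with an estimated correlation. The fibroblast median lay at -0.23 (camera adjusted p = 4.32e-05) and the atrial median at -0.39 (camera adjusted p = 0.00122), each again with an adjusted p = 0.436 with an estimated correlation. Immune markers had a median of -0.33, with 21 of 23 below 0 (camera adjusted p = 4.52e-05, adjusted p = 0.436 with an estimated correlation), and endothelial markers one of -0.23 (camera adjusted p = 0.00436, adjusted p = 0.441 with an estimated correlation). With the preset correlation 22 lists passed, 11 in each direction, against 0 with an estimated correlation and 0 with fry. ND replicate 1 differed from the other ND libraries by -0.40 in the respiratory chain list, by -0.34 in the sarcomere list and by 1.21 in the immediate-early and heat-shock list. It differed by -0.56 in the oxidation list, 0.26 in the fibroblast list and 0.32 in the endothelial list. Each of these was opposite in sign to the sHFD vs ND median. In the atrial (-0.26) and immune (-0.19) lists the sign was the same as that of sHFD vs ND.

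The full and the slight high-fat diet differed most. Aqp7 fell from 61.4 ± 8.24 TPM in sHFD to 4.51 ± 0.80 TPM in HFD (log2 -3.50, SE 0.27, limma adjusted p = 4.54e-05), and Myh7 rose from 180 ± 71.6 to 1115 ± 146 TPM (log2 2.69, SE 0.34, adjusted p = 0.000703). Other large falls were Ucp3 (log2 -3.33), Slc25a34 (log2 -3.14) and Btnl9, a butyrophilin-like gene of capillary endothelium (log2 -2.88), with adjusted p from 0.000356 to 0.00132. The largest rises were Cxcl1 (log2 3.95), Il6 (log2 3.84), Zbtb16, a glucocorticoid-responsive transcription factor (log2 3.75), and Col2a1, the cartilage collagen (log2 3.41), with adjusted p from 0.000696 to 0.00705, together with Scgb3a2, a secretoglobin of airway epithelium. Scgb3a2 was listed at 0 in the 3 sHFD libraries and was 4.11, 3.13 and 174 TPM in the HFD libraries (adjusted p = 0.0486), so no fold is given. It was 52.2, 0 and 0 TPM in the ND libraries and missed the threshold without sHFD replicate 1, 2 or 3 or HFD replicate 3, and with the GC trend removed (adjusted p = 0.0624). Of the 10 genes with the largest changes here, the other 9 passed in all 9 fits with a library left out.

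Of 13655 genes, 4665 passed limma's test, 1406 higher and 3259 lower in HFD, and 1644 of them changed at least 2-fold. The libraries did not overlap in 51.3% of genes, where chance gives 10%, and the median of all genes was -0.16. Median-ratio scaling gave 2571 higher and 2547 lower, and the count was 3037 without sHFD replicate 1, 3092 without sHFD replicate 3 and 2696 without HFD replicate 2. With the mean level of the immediate-early and heat-shock genes in the model, which separates the HFD libraries (8.09 to 8.66) from the sHFD libraries (6.62 to 6.76), 2 genes passed.

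Of 27 immediate-early and heat-shock genes, 25 rose in HFD vs sHFD over all genes and 26 when adjusted over the list alone. Hsp90aa1 rose from 231 ± 28.1 to 473 ± 110 TPM (log2 1.02, SE 0.22, adjusted p = 0.00465), and the list's median lay 1.77 above all genes (camera adjusted p = 8.25e-16, adjusted p = 0.399 with an estimated correlation). Circadian and glucocorticoid genes rose in 16 of 22 cases and fell in 3, over all genes and when adjusted over the list alone, with the clock repressor gene Ciart up by 2.44 (adjusted p = 0.00153) and the median 1.19 above all genes (camera adjusted p = 3.26e-07, adjusted p = 0.399 with an estimated correlation). Of 27 cell-cycle brakes, 14 rose and 1 fell over all genes and when adjusted over the list alone. Cdkn1a rose from 68.4 ± 9.77 to 397 ± 106 TPM (SE 0.52 on the log2 scale, adjusted p = 0.00407) and Trp53 changed by -1.51 (adjusted p = 0.00109). The brakes' median lay 0.69 above all genes (camera adjusted p = 1.15e-06, adjusted p = 0.399 with an estimated correlation). Mitosis genes rose in 21 of 42 cases over all genes, and 22 rose and 1 fell when adjusted over the list alone, Ccnb1 by 1.34 (adjusted p = 0.0018) and Mki67 by 0.61 (adjusted p = 0.0468). Replication and G1/S genes fell in 15 of 40 cases over all genes and in 18 when adjusted over the list alone, Lig1 by 1.09 (adjusted p = 0.00443). The mitosis median lay 0.70 above all genes (camera adjusted p = 1.46e-08, adjusted p = 0.492 with an estimated correlation) and the replication median at -0.39 (camera adjusted p = 0.00578, adjusted p = 0.678 with an estimated correlation). Ccnd1 and Ccnd2 fell by 1.41 and 1.27 (adjusted p = 0.00123 and 0.00449).

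Fatty acid oxidation genes fell in 22 of 30 cases over all genes and in 26 when adjusted over the list alone, with Cpt2 at -1.75 and Cpt1b at -1.09 (adjusted p = 0.00148 and 0.00403). Their median lay at -0.73 relative to all genes (camera adjusted p = 1.45e-06, adjusted p = 0.492 with an estimated correlation). PPAR-responsive and lipid-storage genes fell in 17 of 21 cases over all genes and when adjusted over the list alone, with Angptl4 at -2.12 (adjusted p = 0.000401) and Plin4 at -1.53 (adjusted p = 0.00217). The PPAR median lay at -0.87 (camera adjusted p = 7.27e-06, adjusted p = 0.399 with an estimated correlation). Sterol and fatty acid synthesis genes fell in 13 of 31 cases and rose in 2, over all genes and when adjusted over the list alone, with Dhcr7 at -1.49 (adjusted p = 0.0018), and the list did not pass (camera adjusted p = 0.0548) except under median-ratio scaling (adjusted p = 0.0479). Immune markers fell in 11 of 23 cases and rose in 2 over all genes, and 13 fell and 2 rose when adjusted over the list alone, with Coro1a at -1.28 (adjusted p = 0.00127) and the median at -0.57 (camera adjusted p = 0.00716, adjusted p = 0.53 with an estimated correlation). Pericyte and smooth muscle markers fell in 8 of 14 cases and rose in 1, over all genes and when adjusted over the list alone, with Kcnj8 at -1.44 (adjusted p = 0.000696) and no call for the list (camera adjusted p = 0.0563), which passed under median-ratio scaling and quantile normalization (adjusted p = 0.0426 and 0.0154) but not with an estimated correlation (adjusted p = 0.492 with an estimated correlation). Endothelial markers fell in 6 of 23 cases over all genes and when adjusted over the list alone, Aplnr by 1.31 (adjusted p = 0.000424), with no call for the list (camera adjusted p = 0.855). The list's median was 0.09 above all genes, although camera gave its direction as lower. The share of endothelial markers that fell was similar to that of all genes (3259 of 13655). Erythroid markers fell in 7 of 11 cases over all genes and when adjusted over the list alone, with a median of -0.69 (camera adjusted p = 0.0311, adjusted p = 0.495 with an estimated correlation) that missed the threshold without the haemoglobin genes (camera adjusted p = 0.0848). Atrial markers rose in 4 of 14 cases and fell in 1, over all genes and when adjusted over the list alone, with the median 0.69 above all genes (camera adjusted p = 0.00716, adjusted p = 0.492 with an estimated correlation). Of 13 epicardial markers 2 rose and 1 fell over all genes, and 0 rose and 1 fell when adjusted over the list alone, with the median 0.53 above all genes (camera adjusted p = 0.0314, adjusted p = 0.634 with an estimated correlation). With the preset correlation 21 of 30 lists passed, 15 higher and 6 lower, against 0 with an estimated correlation and 12 with fry.

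The 2 comparisons that share the HFD libraries called many of the same genes. Of 175 genes higher in HFD vs ND, 162 were also higher in HFD vs sHFD, and of 1309 lower genes, 1207 were also lower, where independent lists would share 18.0 and 312, and 0 genes were called in opposite directions. Both comparisons use the same HFD libraries, so the overlap is no independent test. The HFD and sHFD fold changes against the same ND libraries had a Pearson correlation of -0.37 across genes, which are not independent replicates, and a covariance of -0.05. Unchanged groups simulated with the spread pooled over the diets gave a correlation of 0.50 and a covariance of 0.03. With the spread of the ND libraries these were 0.50 and 0.05. Without ND replicate 1 the correlation was -0.07 and the covariance -0.01, and without ND replicate 2 the correlation was -0.14. With 3 ND libraries the controls cannot be split to leave 2 in each part.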

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

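Removing a GC trend and adding the mean level of the immediate-early and heat-shock genes (the stress covariate) were chosen after seeing the data. In HFD vs ND, where 1484 genes passed, the count was 763 with no filter, 420 with only the 2 diets compared, 4700 with array weights, 581 with a fold of at least 2 as well, 512 with the stress covariate and 32 to 3842 with a library left out (the lowest without HFD replicate 2, the highest without ND replicate 1). In sHFD vs ND, where 1 passed in limma, it was 0 with a pseudocount of 0.1 or 5, no filter, a mean of at least 5 TPM, the replicate block or the stress covariate, 2 with only the 2 diets compared, 19 with array weights and 0 to 360 with a library left out. In HFD vs sHFD, where 4665 passed, it was 9331 with array weights, 1644 with a fold of at least 2 as well, 2 with the stress covariate and 2696 to 5458 with a library left out. The cause of these shifts was not tested. The stress covariate does not overlap between HFD and sHFD, so the 2 genes left there cannot tell diet from stress level. The number of lists past camera's test in HFD vs ND was 23, and it was 15 under quantile normalization, 0 with an estimated correlation and 4 with fry. The correlation of -0.37 between fold changes that share the ND libraries was -0.14 with array weights, -0.039 with the stress covariate and -0.41 to -0.074 with a library left out.

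Some directions turned. With the stress covariate, HFD vs sHFD gave fitted values of -1.89 for Scgb3a2 and -0.21 for Col2a1 that did not pass the test (limma adjusted p = 0.657 and 0.925), the first no fold, since that gene was listed at 0 in sHFD. List medians turned from -0.39 to 0.15 for DNA replication (camera adjusted p = 0.0631), and from -0.16 to 0.40 for the mature sarcomere, from -0.20 to 0.35 for calcium handling, from -0.0053 to 0.35 for cardiac transcription factors and from -0.18 to 0.37 for the respiratory chain, and these 4 passed in the turned direction at the preset correlation (camera adjusted p = 3.76e-05, 0.000429, 0.00646 and 2.47e-07). With the covariate, sHFD vs ND turned from 0.16 to -0.18 for DNA replication, which passed at the preset correlation (camera adjusted p = 0.000156). It gave values that did not pass of -0.0066 for calcium handling, -0.041 for cholesterol synthesis and 0.058 for endothelial markers. No list was tested with an estimated correlation in the fits with the covariate. Its levels do not overlap between HFD and sHFD, so the turned HFD vs sHFD values are extrapolated and cannot tell diet from stress level. Within diets the covariate varied most in ND (8.47, 6.64 and 7.65 in replicates 1 to 3), so the fit leans on those libraries. DNA replication in sHFD vs ND was -0.018 with array weights and -0.035 to 0.27 with a library left out, turning without ND replicate 1 (-0.035) and sHFD replicate 2 (-0.0034). Ribosomal proteins ran from -0.023 (without ND replicate 2) to 0.38 in HFD vs ND, and from -0.34 to 0.11 in sHFD vs ND, turning without ND replicate 3 (0.011) and sHFD replicate 2 (0.11).

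With the replicate number as a block, 1686 genes passed in HFD vs ND, 4722 in HFD vs sHFD and 25 lists in HFD vs ND. The deviations of libraries with the same number in different diets correlated above 0.1 in 4 of 9 pairs (-0.29 to 0.41, beside -0.35 to 0.35 for different numbers), and 4 of 9 libraries correlated best with 1 of their own number. The counts expected by chance were not computed, so these values do not show that the number marks a batch.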

Other observations

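The full high-fat diet differed from the slight one in further genes. Hippo-YAP targets rose in 9 of 19 cases over all genes tested and in 10 when adjusted over the list alone, with Amotl1 up by 0.79 (limma adjusted p = 0.002) and Ccn2 by 1.53 (adjusted p = 0.00505), and the list's median lay 0.62 above all genes (camera adjusted p = 0.000111, adjusted p = 0.492 with an estimated correlation). Of 27 ER stress genes, 7 rose and 1 fell over all genes and when adjusted over the list alone, among them the chaperone gene Hspa5 (log2 1.12, adjusted p = 0.00312) and Atf4, the factor of the integrated stress response (log2 1.21, adjusted p = 0.00261). Their median lay 0.40 above all genes (camera adjusted p = 0.000885, adjusted p = 0.399 with an estimated correlation). Ion channel genes fell in 8 of 29 cases over all genes and in 4 when adjusted over the list alone, among them Kcnj11 (log2 -1.45, adjusted p = 0.00215), with no call for the list (camera adjusted p = 0.179). Among all 13655 genes tested 3259 fell, a similar share.

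The imprinted gene Dlk1, a Notch-like regulator of fetal growth, rose from 254 ± 16.0 TPM in sHFD to 398 ± 33.5 TPM in HFD (log2 0.65, limma adjusted p = 0.019), and Peg10, a retrotransposon-derived placental gene, rose by 1.12 (adjusted p = 0.00653). Of 16 imprinted genes, 4 rose over all genes and 4 when adjusted over the list alone, and the list's median lay 0.28 above all genes (camera adjusted p = 0.0366, adjusted p = 0.492 with an estimated correlation), which missed the threshold under quantile normalization (median 0.08, camera adjusted p = 0.277) and with the GC trend removed (camera adjusted p = 0.0652). In the insulin and IGF list the phosphoinositide kinase subunit gene Pik3r1 rose by 0.97 (adjusted p = 0.0044) and the growth factor receptor gene Igf1r by 0.74 (adjusted p = 0.00979), among 8 of 26 that rose and 1 that fell over all genes, and 9 and 1 when adjusted over the list alone. That median lay 0.46 above all genes (camera adjusted p = 0.00513, adjusted p = 0.492 with an estimated correlation) and missed the threshold under quantile normalization (camera adjusted p = 0.0588).

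The tests below were chosen after the results were seen, except those of the airway and cartilage markers, which were written before the values of these markers were looked at.

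ND replicate 1 lay nearer the HFD libraries than the other ND libraries did. Over 4059 to 5800 genes chosen without each HFD library in turn, and on a scale with the sHFD mean at 0 and the mean of the other HFD libraries at 1, the median position of ND replicate 1 was 0.671 to 0.767, at most 0.0596 and 0.235 for ND replicates 2 and 3, and 0.833 to 0.981 for the held-out library, which lay 0.162 to 0.214 above ND replicate 1 on the same genes. Among 31 lists, 9 put ND replicate 1 outside the range of the HFD libraries by more than that range, such as epicardial markers (-0.06 beside 0.52 to 0.57 relative to ND replicates 2 and 3), immune markers (-0.19 beside -0.97 to -0.67) and calcium handling (-0.44 beside -0.08 to -0.05). HFD replicate 3, set in the same way against ND replicate 1 and the other HFD libraries, lay outside in 6 lists (HFD replicates 1 and 2 in 0). Over 13655 genes, 2284 put ND replicate 1 outside in this way, and 1261, 771 and 1855 did so for HFD replicates 1 to 3. The correlation of HFD replicate 3 with ND replicate 1 was 0.983, beside 0.980 and 0.983 with HFD replicates 1 and 2. These values cannot decide whether ND replicate 1 is an HFD library under the wrong label. The immediate-early and heat-shock list was higher in ND replicate 1 by 1.21 relative to all genes, at percentile 100 of 10000 matched random lists, but so was the circadian list, and of the other 30 lists 7 lay above percentile 99 and 10 under percentile 1, among these the oxidation, sarcomere, calcium handling and respiratory chain lists. A stress response of the cells therefore stays open without being singled out, and whether it arose in the animal or during isolation was not tested.

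Immune cell markers fell in HFD vs ND. Of the 23 measured, 91.3% lay below the median change of all genes, with quartiles of -0.99 and -0.62, which restates the fall and does not test its source. In ND replicate 1 the markers differed by -0.19 from the other ND libraries (95% bootstrap interval over the markers -0.21 to 0.05), where -0.38 would make up 0.5 of the median of -0.76, but 1 library excludes nothing. Fewer immune cells in the HFD isolates, the response seen in ND replicate 1, lower transcription within immune cells, and an effect of diet on them stay open.

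Airway secretory genes and Col2a1 were highest in ND replicate 1 and HFD replicate 3. Scgb3a2 was 52.2 and 174 TPM there, and Col2a1 84.9 and 54.4 TPM. Of 18 further airway markers that reached 1 TPM, 6 had these as their 2 highest libraries (exact binomial p = 6.39e-06), as did 9 of 16 cartilage markers (exact binomial p = 9.44e-11), where 1 of 36 pairs is expected and markers of a tissue are not independent. That expectation treats all pairs as equally likely. These 2 libraries also had the lowest scores on the second principal component (-17.9 and -25.2) and a correlation of 0.983 over all genes. The share of all genes with this pair highest was not counted, so the p-values do not set the markers apart from other genes. Traces of airway epithelium and cartilage in these isolates are candidate sources. Distal lung stays open: the ratio of the surfactant gene Sftpc to Scgb3a2 was at most 0.0012, but Sftpd was 2.14 TPM in HFD replicate 3 and 0 elsewhere, and Sftpb was highest there (1.28 TPM), although 0 of these 2 had ND replicate 1 and HFD replicate 3 as their 2 highest libraries. Some cartilage markers were present in all 9 libraries, with Col9a2 at 19.1 TPM or more in each, and no biological explanation was tested.

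The 6 libraries of a comparison can be split in 10 ways, too few for a share under 0.05. Every other split mixes the diets in both groups, so a separation of any cause widens the spread within groups and lowers the count. Low counts in the other splits therefore say little about what separates the libraries. In HFD vs ND the real split gave 1484 genes and the highest other 0, with 1 of 10 splits as large. In sHFD vs ND these were 1 and 1, with 2 of 10 splits as large, and in HFD vs sHFD 4665 and 0, with 1 of 10 as large.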
